A study of Mus musculus with 5 samples.

How the data were processed

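Single-cell RNA libraries were made from pancreatic islets of mice with a floxed Atf6a gene. ATF6α is a transcription factor that is released from the endoplasmic reticulum membrane when unfolded proteins accumulate. Control mice carried the floxed alleles without Cre, and the knockout (cKO) mice also carried RIP-Cre, a recombinase driven by a rat insulin promoter that acts mainly in beta cells. The mice received a normal diet with 10% of energy as fat or a high-fat diet with 60%, from 6 weeks of age, and islets were taken at 22 weeks. Per the labels' protocols, islets were released with collagenase, picked by hand, pooled from 2 mice per library, dissociated with accutase and run on the 10x Genomics 5′ chemistry.

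The deposited tables assign each cell to a library, a cell type, a numbered cluster and a position in a 2-dimensional UMAP embedding. None of these values is a read count or an expression level, and expression per gene was not analysed here. Per the submitters' processing notes, Cell Ranger 7.1.0 and the mouse build GRCm39 were used. The filters on cells, the treatment of doublets, any batch integration, the clustering settings and the rule that named the cell types are not given in the sources used here. All of these steps set which cells are counted and in which class, and they precede every value reported. The sequencing depth per library and per cell is unknown here, so precision is set by the number of cells.

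The 4 tables were joined by cell identifier, and all 18221 cells occurred in each of them. A cell's library came from the library name in the tables, matched to the sample titles by genotype, diet and number. The number in the names of both cKO normal-diet libraries was read as the batch number in the titles. The 5 libraries fell into 4 groups. Control normal diet, control high-fat diet and cKO high-fat diet had 1 library each, all of batch 1. The cKO normal-diet group had 2 libraries, 1 of batch 1 and 1 of batch 2. No annotated class was unknown, mixed or low quality, and all cells of a cluster had the same cell type (0 exceptions). Doublets were not called here, since that needs counts per gene.

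For each library the share of a cell type was taken over all its cells, and the share of a beta cluster over its beta cells, each with an exact (Clopper-Pearson) 95% binomial interval. A count of 0 was given an upper limit of 3 cells of the total. These intervals and limits cover counting error only, not the variation between mice or preparations. The shares of a library have a fixed sum, so a higher share of 1 class lowers those of the others. The cKO normal-diet group is the equal-weight mean of its 2 libraries with their SD. Groups were compared by the log2 ratio of shares, with a 95% counting interval by the delta method. Because most groups held 1 library, no p-value was computed from cells. A ratio was called larger than the replicate gap when its interval excluded 0 and its size exceeded the log2 ratio between the 2 cKO normal-diet libraries for the same class. Because this gap has counting error of its own, it is given with a 95% delta-method interval, computed after the data were seen, where both libraries had cells of the class and a call depends on it. Where 1 of these libraries had 0 cells of a class, the gap was only a lower limit, and a ratio above that limit was left undetermined. The gap comes from a single pair of libraries, so a ratio can also exceed it through variation between libraries without an effect of genotype or diet. Comparisons needed at least 20 cells. Within-batch values that use the batch 1 cKO normal-diet library alone are given beside the means.

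Genotype and diet were also each pooled over the other factor and compared by a two-sided exact permutation test over the 5 libraries, with Benjamini-Hochberg adjustment within each family. Its 10 splits give no p below 0.1. Library mixing was described by the 30 nearest neighbours of each beta cell in the deposited embedding, as the observed over the expected share of neighbours from each library. Distance in a UMAP embedding is not distance in expression. On simulated data, the 95% interval covered the true log2 ratio in 93.6% to 94.8% of 2000 draws for each of 10 simulated comparisons of beta and immune shares. Over 20 shuffles of the library names among the real beta cells, the neighbour ratio lay between 0.971 and 1.02 for the 3 largest libraries, between 0.792 and 1.22 over the 4 larger ones, and between 0 and 2.82 for the 31 beta cells of the smallest.

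Comparisons, the rule for calls and a set of alternatives were fixed before the data were examined. These alternatives were endocrine cells as the denominator, odds ratios, the cell type by cluster majority, the largest replicate gap as the yardstick, leaving out each cKO normal-diet library, other neighbour numbers and equal numbers of cells per library. Summed cKO normal-diet cells, the counting interval as the sole rule, and the settings that leave out the 40-cell library under that rule, in the mixing measure and in the permutation test were added after the data were seen. Every cell type with at least 20 cells is named, and clusters are named where they passed the rule or were the largest beta cluster of a library. Other beta clusters were named after their values were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.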

Results

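The cellular makeup of isolated mouse islets was compared between control mice and mice lacking ATF6α in beta cells, on a normal and on a high-fat diet. The 18221 annotated cells fell into 8 cell types and 14 clusters. Beta cells, which secrete insulin, made up 6 of the clusters, and glucagon-secreting alpha cells made up 2. Somatostatin-secreting delta cells, PP cells (the pancreatic polypeptide cells), immune, endothelial, neuron and acinar cells had 1 cluster each. The libraries held 7998 cells (control, normal diet), 6667 cells (control, high-fat diet), 2483 cells (cKO, high-fat diet), and 40 and 1033 cells (cKO, normal diet, batches 1 and 2). Each library came from islets pooled from 2 mice, so replicates differ in mice and batch together. The cell numbers differed from 40 to 7998 under filters not given in the sources used here, and shares depend on which cells were recovered.

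The pair of cKO normal-diet libraries, the sole replicates of the design, differed widely. Beta cells were 31 of 40 cells in batch 1, or 77.5% (exact 95% interval 61.5 to 89.2%), and 236 of 1033 cells in batch 2, or 22.8% (20.3 to 25.5%). The batch 1 library had no alpha, delta or PP cell, which allows up to 7.50% of each, whereas the batch 2 library had 31.2% alpha, 28.8% delta and 8.23% PP cells. Immune cells were 17.5% (7.34 to 32.8%) in batch 1 and 7.16% (5.67 to 8.91%) in batch 2. The group means were 50.2% ± 38.6 (SD, n = 2) for beta cells and 12.3% ± 7.31 (SD, n = 2) for immune cells. On the log2 scale this replicate gap was 1.76 for beta cells and 1.29 for immune cells, and it was at least 2.06 for alpha cells and at least 1.94 for delta cells. The gap has its own counting error, with a 95% interval of 1.47 to 2.05 for beta cells and 0.27 to 2.31 for immune cells.

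**Figure D1:**
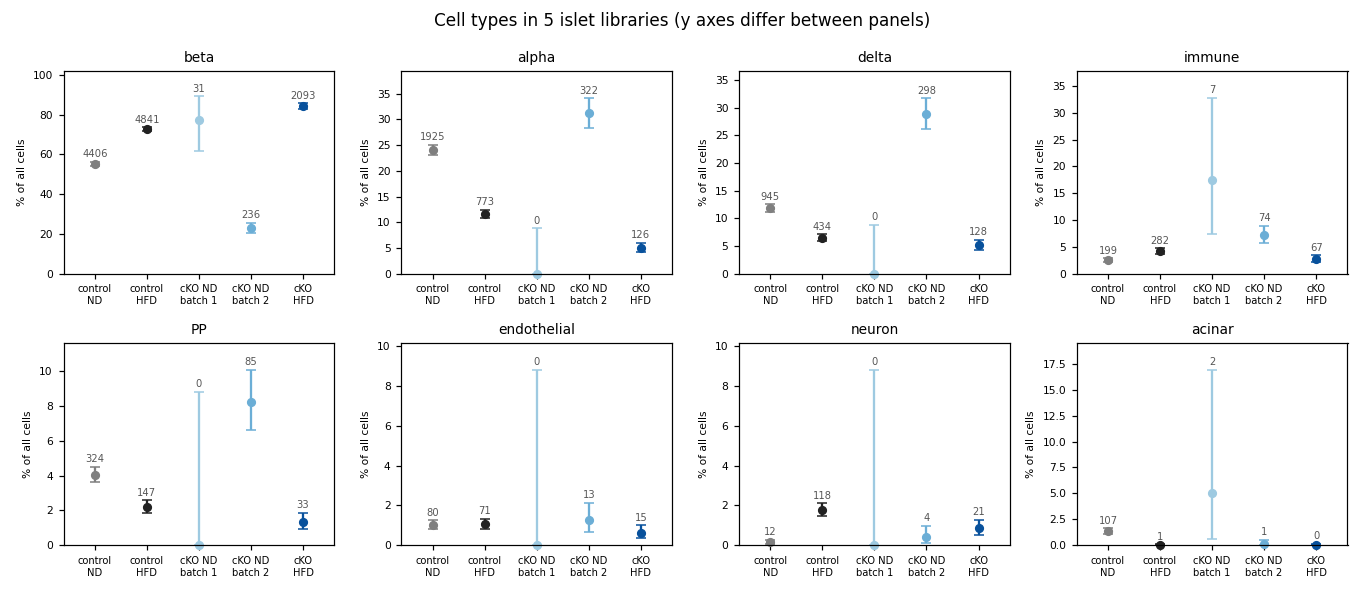
Share of each annotated cell type in percent of all cells (y axis) in each of the 5 islet libraries (x axis; ND normal diet, HFD high-fat diet). Points are single libraries, bars are exact 95% binomial intervals for counting error, and the grey number is the cell count; beta cells ranged from 22.8% in the batch 2 cKO normal-diet library to 84.3% in the cKO high-fat library.

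High-fat feeding of control mice addressed how the islet cell composition differs with diet when ATF6α is present. Beta cells made up 72.6% (71.5 to 73.7%) of cells in the high-fat library and 55.1% (54.0 to 56.2%) in the normal-diet library, a log2 ratio of 0.40 (95% counting interval 0.36 to 0.43). The other endocrine types were all lower in the high-fat library: alpha cells at 11.6% against 24.1%, delta cells at 6.51% against 11.8%, and PP cells at 2.20% against 4.05%. With a fixed sum of shares, these lower shares are not independent of the higher beta cell share. There were 6.26 beta cells per alpha cell (5.80 to 6.76) in the high-fat library and 2.29 (2.17 to 2.41) in the normal-diet library. Immune cells were higher at 4.23% (3.76 to 4.74%) against 2.49% (2.16 to 2.85%), and cells annotated as neurons at 1.77% (118 cells) against 0.150% (12 cells). Endothelial cells were 1.06% and 1.00%, with a log2 ratio of 0.09 (-0.37 to 0.55). Acinar cells, the enzyme-secreting cells of the exocrine pancreas, were 1 of 6667 cells against 107 of 7998, a log2 ratio of -6.48 (-9.32 to -3.64).

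Within the control beta cells, cluster 3 was 17.7% (16.6 to 18.8%) of beta cells in the high-fat library and 3.88% (3.33 to 4.49%) in the normal-diet library, 4.55-fold higher (3.88 to 5.34). Cluster 7 was also higher, at 17.2% against 7.47%, and cluster 5 at 19.4% against 14.3%. Cluster 1, the largest in both control libraries, was 35.5% in the high-fat and 55.4% in the normal-diet library, and cluster 6 was 9.03% and 17.3%. Cluster 9 was 1.20% and 1.61%, with a log2 ratio of -0.43 (-0.92 to 0.07). The counting interval excluded 0 for 7 of 8 cell types and 5 of 6 beta clusters, and the lower acinar share alone had a log2 ratio above its replicate gap. That acinar gap, 5.69 (2.26 to 9.12), rests on 2 and 1 cells, so it gives no usable yardstick. PP cells, neurons and beta clusters 3 and 6 were undetermined.

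In cKO mice the same diets were compared across batches. Beta cells were 84.3% (82.8 to 85.7%) of the high-fat library, above the group mean of 50.2% on normal diet by a log2 ratio of 0.75 (0.56 to 0.94), which is below the replicate gap. Against the batch 1 library alone, the within-batch value, the log2 ratio was 0.12, and against the batch 2 library alone it was 1.88 (1.72 to 2.05), above that gap but within its interval. Alpha cells were 5.07%, delta cells 5.16% and PP cells 1.33% in the high-fat library, each below its share in the batch 2 normal-diet library and within what 0 of 40 cells allows in batch 1. Immune cells, at 2.70% (2.10 to 3.41%) in the high-fat library, were lower than the mean of both normal-diet libraries by a log2 ratio of -2.19 (-2.97 to -1.42). This was the sole difference between cell types larger than the replicate gap of 1.29, though within the upper limit of that gap, and it held in direction against each library (log2 ratio -2.70 for batch 1 and -1.41 for batch 2). Neurons were 0.846% (21 cells) in the high-fat library, against 0 of 40 cells and 4 of 1033 cells (0.387%). Acinar cells were absent among 2483 cells, which allows up to 0.121%, and the 3 acinar cells in all were too few to compare. Endothelial cells were 0.604% in the high-fat library and 1.26% in batch 2, and PP cells and neurons were undetermined.

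Beta cluster 3 was the largest cluster of the cKO high-fat library, at 42.0% (39.9 to 44.1%) of beta cells, against 24.2% (18.8 to 30.1%) in the batch 2 normal-diet library and 0 of 31 beta cells in batch 1. Cluster 1 was 5.30% against 37.3% in batch 2. Cluster 9 was 23.1% (21.3 to 25.0%) against 19.5% (14.6 to 25.1%) in batch 2 and 3.23% (1 cell, 0.082 to 16.7%) in batch 1. In the batch 1 normal-diet library, 21 of the 31 beta cells were in cluster 5, its largest, and 9 in cluster 7. None of the 6 clusters differed between diets by more than the replicate gap, and clusters 3 and 6 were undetermined. Against batch 1 alone, cluster 9 passed its uncertain gap with a log2 ratio of 2.84 (0.06 to 5.63), whereas against batch 2 alone its log2 ratio was 0.25 (-0.14 to 0.64).

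The comparison of genotypes on normal diet depended on which cKO library was used. The beta cell share was 55.1% in the control library, and the cKO mean differed from it by a log2 ratio of -0.13 (-0.33 to 0.06). Within batch 1 the cKO share was above the control (log2 ratio 0.49), and the batch 2 library was below it (-1.27). Delta cells of the batch 2 library, at 28.8%, lay above the 11.8% of the control (log2 ratio 1.29), and its alpha cells, at 31.2%, lay above 24.1% (0.37). PP cells were 8.23% in batch 2 and 4.05% in the control. Endothelial cells were 1.26% (13 cells) in batch 2 and 1.00% in the control. Neurons numbered 16 over the libraries compared, too few under the rule. Acinar cells were 2 of 40 and 1 of 1033 in the cKO libraries, against 1.34% in the control. Immune cells were above the 2.49% of the control in both cKO libraries, with a log2 ratio of 2.31 (1.59 to 3.03) for the mean, 2.81 within batch 1 and 1.53 for batch 2. Immune cells were the 1 of 8 cell types with a ratio above the replicate gap, and the ratio lies within the upper limit of that gap, 2.31.

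Among beta cells on normal diet, cluster 9 was 1.61% (1.26 to 2.03%) in the control, and its mean in the cKO libraries was 11.4% ± 11.5 (SD, n = 2), a log2 ratio of 2.82 (2.21 to 3.43). It was the 1 cluster of 6 with a ratio above the replicate gap of 2.60. With 1 cluster 9 cell in batch 1, that gap has an interval of -0.21 to 5.40 and is itself undetermined. The batch 2 library alone gave a log2 ratio of 3.60, and the within-batch ratio was 1.00 (-1.80 to 3.80). Cluster 3 was 24.2% in batch 2 against 3.88% in the control, and it was undetermined, as was cluster 6.

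**Figure D2:**
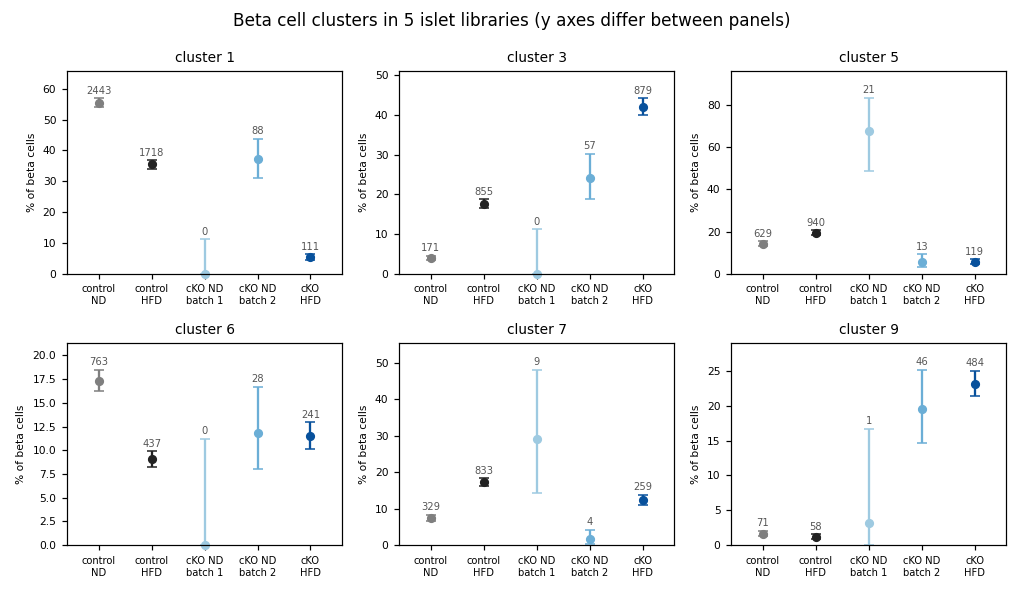
Share of each of the 6 beta cell clusters in percent of a library's beta cells (y axis) in each of the 5 libraries (x axis; ND normal diet, HFD high-fat diet). Points are single libraries, bars are exact 95% binomial intervals for counting error, and the grey number is the cell count; cluster 9 was 1.20% to 1.61% in the control libraries and 19.5% and 23.1% in both larger cKO libraries.

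On the high-fat diet both genotypes came from batch 1. The cKO library had a beta cell share of 84.3% (82.8 to 85.7%) and the control library 72.6% (71.5 to 73.7%). The log2 ratio was 0.22 (0.18 to 0.25). Cells of beta cluster 9 were 19.5% of all cells in the cKO library and 0.870% in the control library. This exceeds the difference in beta share, so the direction of that difference depends on counting cluster 9 as beta cells. The 6 other cell types with enough cells were all lower in the cKO library. Because shares have a fixed sum, these lower shares are not independent of the higher beta cell share. Alpha cells were 5.07% against 11.6% (log2 ratio -1.19), delta cells 5.16% against 6.51% (-0.34), PP cells 1.33% against 2.20% (-0.73), and immune cells 2.70% against 4.23% (-0.65). Endothelial cells were 0.604% against 1.06% (-0.82) and neurons 0.846% against 1.77% (-1.07), whereas acinar cells, with 1 cell over both libraries, were too few. There were 16.6 beta cells per alpha cell (13.9 to 19.9) in the cKO library and 6.26 (5.80 to 6.76) in the control. The counting interval excluded 0 for all 7 types compared, but none was larger than the replicate gap, and 3 types (PP, endothelial, neuron) were undetermined.

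Among beta cells, cluster 9 was 23.1% (21.3 to 25.0%) of beta cells in the cKO high-fat library and 1.20% (0.911 to 1.55%) in the control, 19.3-fold higher, with a log2 ratio of 4.27 (3.88 to 4.66). Cluster 3 was 42.0% against 17.7% (log2 ratio 1.25). Cluster 1 was lower, at 5.30% against 35.5% (-2.74), as was cluster 5, at 5.69% against 19.4% (-1.77). Cluster 7 was 12.4% against 17.2%, and cluster 6 was 11.5% against 9.03%. Cluster 9 was the 1 cluster with a ratio above its replicate gap, 2.60 (-0.21 to 5.40), which 1 cell of batch 1 sets and which therefore decides no call. Clusters 1 and 6 were undetermined. Clusters were used as deposited, and where cluster membership follows expression, a cell whose expression shifts with genotype or diet is counted in another cluster.

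The ratio of the diet ratios, cKO over control, addressed whether composition differed with diet to another extent without ATF6α. For beta cells it was 0.35 on the log2 scale (0.16 to 0.54), below the replicate gap, and its sign changed with the normal-diet cKO library: -0.28 within batch 1 and 1.49 with batch 2. For immune cells it was -2.96 (-3.77 to -2.14), the 1 value of 8 larger than the replicate gap, and past the upper limit of that gap, 2.31. That limit covers counting error only. The value combines all groups, whereas the gap compares a single pair of libraries, so differences between libraries alone can exceed the gap. The immune value was -3.46 within batch 1 and -2.17 (-2.71 to -1.64) with batch 2. With batch 2 it was thus larger than the gap but within its upper limit. Immune cells were higher on the high-fat diet in control mice and lower in cKO mice, whichever cKO normal-diet library was used. PP and acinar cells were undetermined. None of the 6 beta clusters passed, cluster 6 was undetermined, and cluster 9 had a log2 value of 1.45 (0.73 to 2.17). With the batch 1 cKO normal-diet library alone, clusters 5 and 9 passed, within the intervals of their gaps, with log2 values of -4.02 and 3.27, whereas with batch 2 alone these were -0.40 and 0.67.

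When the 5 libraries were pooled by 1 factor, no comparison could reach a p below 0.1. Of 8 cell types, 0 separated the 3 cKO from the 2 control libraries completely, and 2 (neurons and acinar cells) separated the 2 high-fat from the 3 normal-diet libraries, where chance gives 20% of types. The 0 neurons of the 40-cell library allow up to 7.50%, so their separation rests on the 4 other libraries. The acinar separation rests on 1 of 1033 cells in the batch 2 normal-diet library (0.00245 to 0.538%), within counting error of the high-fat libraries. Of 6 beta clusters, cluster 9 alone separated the genotypes (15.3% mean in cKO and 1.40% in control libraries, two-sided exact permutation p = 0.20, adjusted p = 0.90), and none separated the diets. Cluster 9 lay above both controls in the batch 1 cKO library by 1 cell of 31 (0.082 to 16.7%), so its separation there is within counting error. Without the batch 2 library 5 cell types and 2 clusters separated the genotypes. However, 4 of these types (alpha, delta, PP, endothelial) had 0 of 40 cells. The 7.50% allowed exceeds the high-fat control share of delta cells (6.51%) and both control shares of PP and endothelial cells. Without the 40-cell library 6 cell types separated the diets and 3 clusters the genotypes, where chance gives 33.3%. The lowest adjusted exact permutation p over the 8 cell types was 0.69 for diet and 1 for genotype.

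In the deposited embedding, beta cells lay next to beta cells of their own library more often than their numbers gave. The ratio of observed to expected neighbours from the same library was 1.47 in the control normal-diet library, 1.37 in the control high-fat library, 3.55 in the batch 2 cKO normal-diet library and 2.90 in the cKO high-fat library. For the 31 beta cells of the batch 1 cKO normal-diet library it was 99.4, where shuffled library names gave at most 2.82, but 1.62 with 31 beta cells drawn from each library. Beta cells of the cKO high-fat library had 1.40 times the expected neighbours from the batch 2 cKO normal-diet library, 0.64 times those from the control high-fat library and 0.48 times those from the control normal-diet library. With 236 beta cells drawn from each of the 4 larger libraries, the order differed: 1.44 in the batch 2 cKO normal-diet library, 1.55 and 1.57 in the control normal-diet and high-fat libraries, and 1.80 in the cKO high-fat library.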

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

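The tests of explanations in this part were chosen after the results had been seen, whereas the comparisons and the permutation test were fixed beforehand.

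In control mice the high-fat library lay on 1 side of the normal-diet library, and in cKO mice it lay on the opposite side of both normal-diet libraries, for 2 classes. Immune cells had a log2 ratio of diet ratios of -2.96 (cKO over control), and beta cluster 9 had 1.45. With the batch 1 cKO normal-diet library alone these were -3.46 and 3.27, and with batch 2 alone -2.17 and 0.67. The immune value with batch 2 alone lay within the upper limit of the replicate gap, 2.31. The difference was not tested across libraries, since all but 1 group held 1 library. For cluster 9 the diet ratio within control mice had a counting interval that included 0 (-0.43, -0.92 to 0.07), so the opposite directions are within counting error there.

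Beta cluster 9 had the largest log2 ratio between genotypes on the high-fat diet among the cell types and beta clusters compared, and on normal diet for the mean of both cKO libraries but not within batch 1. A batch difference is argued against for the high-fat pair, since both libraries were of batch 1 and their log2 ratio was 4.27 (lower limit 3.88). For the high-fat cKO library, droplets holding a beta cell and another endocrine cell would need at least 0.843 doublets per single cell to give its 484 cluster 9 cells from 287 alpha, delta and PP cells, beside 0.0111 and 0.0214 for the control libraries, which argues against doublets there. For the normal-diet pair, batch stays open (log2 ratio 1.00 within batch 1, -1.80 to 3.80), as do doublets (0.0326 needed per single cell, and the doublets in the library are unknown) and low cell recovery, since the 40-cell library allows up to 16.7% in cluster 9. Genotype is a candidate explanation that the design names, but the 10 splits of the libraries give no share under 0.05 (exact permutation p = 0.20), and the RIP-Cre transgene, the floxed deletion and the particular mice cannot be told apart.

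The batch 1 cKO normal-diet library is the other pattern to follow up, because several calls differed when it was left out. Its 40 cells had no alpha, delta or PP cell, and 30 of its 31 beta cells (96.8%) were in clusters 5 and 7, which held 7.20% of the beta cells of batch 2. Counting error around the makeup of batch 2 is argued against by the lower limit of its beta share, 61.5%, which lies above the upper limit of 25.5% in batch 2. None of its barcodes was listed in another library (0 of 40, exact 95% binomial upper limit 8.81%), which argues against reads carried over from cells kept in the other libraries. Selection of cells by filters before deposit stays open, because the tables list the 40 kept cells and none of those removed, and no biological explanation was tested, as both libraries have the same genotype and diet.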

How the results depend on the processing

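The settings with summed cells, with the counting interval as the sole rule and without the 40-cell library in the permutation test or the equal-number mixing were chosen after the data were seen. With the counting interval as the sole rule, differing cell types numbered 7 for diet in control, 6 for diet in cKO, 3 for genotype on normal diet, 7 for genotype on high-fat diet and 5 for the difference of diet effects, and beta clusters 5, 5, 6, 6 and 5. Leaving out the 40-cell library as well gave 5, 6 and 6 cell types and 3, 6 and 5 clusters for the 3 comparisons that use it. With the largest replicate gap (acinar cells) as yardstick, 0 cell types passed for diet in cKO, genotype on normal diet and the difference of diet effects. Under the original rule, leaving out 1 cKO normal-diet library gave 1 to 2 cell types for diet in cKO (beta cells pass without batch 1), and 0 to 1, 0 to 1 and 0 to 2 beta clusters for diet in cKO, genotype on normal diet (cluster 9 lost without batch 2) and the difference of diet effects. When a library was left out under this rule, the yardstick was still the gap between both libraries, so it still depended on the 40-cell library. The cKO normal-diet beta to alpha ratio was 3.22 as a mean, 0.733 without batch 1, at least 10.3 without batch 2 and 0.829 with cells summed. As log2 odds ratios, beta cells gave 1.11 for diet in control, 2.41 for diet in cKO and 1.02 for genotype on high-fat diet, larger by construction for a share above 50%. Among endocrine cells alone the last log2 ratio of shares was 0.17. Over 4 libraries, where chance separates 33.3% of classes, complete separation held for 5 cell types and 2 clusters by genotype and 1 cluster by diet without batch 2, and for 6 cell types by diet, 3 clusters by genotype and 3 by diet without the 40-cell library. The median same-library neighbour ratio was 2.90 with all beta cells, 1.36 with 31 per library and 1.56 with 236 and no 40-cell library. Except for the odds ratios, the cause of these differences was not tested. Taking cell types or beta cells from cluster majorities could not change any value, because each cluster holds 1 cell type. Of the 170 other distinct alternatives for log2 ratios of cell types other than beta and of beta clusters, 151 kept their sign. The 170 include 61 log2 odds ratios, and those between 2 groups cannot differ in sign from the ratio of shares. The count of kept signs is therefore partly fixed in advance. The beta cell ratio turned sign for genotype on normal diet (-0.13, but 0.49 without batch 2 and 0.11 among endocrine cells) and for the difference of diet effects (0.35, but -0.28 without batch 2). No class was annotated as unknown or low quality, so leaving such cells out could not be run. No paired analysis was possible because the groups share fewer than 2 replicate numbers.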

Other observations

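The ratios between alpha, delta and PP cells, the alpha clusters, the embedding neighbours and both explanations for the beta cell share were examined after the results had been seen.

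In the 4 libraries that held alpha and delta cells, their ratio was lower in both cKO than in both control libraries and close between diets within a genotype. There were 2.04 alpha cells per delta cell (1.88 to 2.20) in the control normal-diet library and 1.78 (1.58 to 2.00) in the control high-fat library, against 1.08 (0.923 to 1.26) in the batch 2 cKO normal-diet library and 0.984 (0.770 to 1.26) in the cKO high-fat library. The log2 ratio of control over cKO was 0.91 (0.66 to 1.17) on normal diet and 0.86 (0.46 to 1.25) on high-fat diet, whereas high-fat over normal diet gave -0.19 (-0.40 to 0.01) in control and -0.13 (-0.56 to 0.29) in cKO mice. Alpha cells per PP cell were 5.94 and 5.26 in the control and 3.79 and 3.82 in the cKO libraries (normal diet, then high-fat diet). The log2 ratio of control over cKO was 0.65 (0.26 to 1.03) on normal diet and 0.46 (-0.15 to 1.07) on high-fat diet. Delta cells per PP cell were 2.92 and 2.95 in the control and 3.51 and 3.88 in the cKO libraries, with overlapping intervals. With 2 libraries against 2, an exact permutation test gives no p below 0.333, which is the value for the alpha to delta ratio.

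Alpha cells were split over clusters 2 and 8. Cluster 8 held 33.3% (31.2 to 35.5%) of alpha cells in the control normal-diet, 31.8% (28.6 to 35.2%) in the control high-fat and 31.0% (23.0 to 39.8%) in the cKO high-fat library, but 58.1% (52.5 to 63.5%) in the batch 2 cKO normal-diet library, the sole library of its batch. The 30 nearest cells in the embedding were counted for each beta cell, cells of its own cluster included. For cluster 9, 69.3% were beta cells (64.4% of cluster 9 itself), 16.1% alpha, 7.51% delta and 6.97% PP cells. Beta cells of other clusters were thus fewer around cluster 9 than cells of each of these types. For cluster 3, 76.6% were beta cells (53.6% of cluster 3 itself), 15.6% alpha and 4.99% PP cells. The other 4 beta clusters had 94.9% to 99.8% beta cells, counted in the same way.

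The higher beta cell share of the high-fat control library was tested against recovery of acinar, endothelial, immune and neuron cells. Among endocrine cells alone the log2 ratio over the normal-diet library was 0.43 (lower limit 0.40), which argues against recovery of those types. They were few, as endocrine cells were 7600 of 7998 cells on normal diet and 6195 of 6667 on high-fat diet. Unequal recovery of alpha, delta and PP cells against beta cells was not tested. A difference between pools of 2 mice that is unrelated to diet may also account for the higher beta cell share, and this stays open. The 2 cKO normal-diet pools differed by a log2 ratio of 1.76, more than the 0.40 between the diets.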
